A study of Danio rerio with 9 samples.

How the data were processed

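The samples were 9 zebrafish melanomas, 5 with MiniCoopR CDK13 R860Q and 4 with MiniCoopR EGFP, grouped by the CDK13 status in the labels. Per the labels' protocols, embryos at the zygote stage were injected with 20 ng per µL of vector DNA and RNA for the Tol2 transposase, fish were raised 20 to a tank, and raised tumours were dissected. RNA was cleared of genomic DNA and depleted of ribosomal RNA, and randomly primed libraries were made after 15 min of fragmentation with 12 PCR cycles and sequenced as 100-bp read pairs on an Illumina HiSeq. Random priming of total RNA also captures unspliced and non-polyadenylated RNA. Per the labels' protocols the kit was a NEBNext Ultra kit, and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands may not be separated.

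Per the submitters' processing notes, Bowtie, HTSeq and the genome build danRer10 (GRCz10) were used, with no versions given. The deposited values are raw counts per gene symbol, not normalised, with 30649 named rows in each of the 9 tables. Each table opens with 1 line that holds neither a name nor a count, which was left out. Rows for reads outside genes are not among the rows used here. Genes with near-identical copies (the ccl34a, nkl, globin, parvalbumin and Mx genes, for example) can share reads, and their split between copies is uncertain. The annotation behind the counts was not used here, and no coordinates are given. Gene neighbours were looked up among the protein-coding genes of NCBI RefSeq's table for GRCz12tu, another build. Of the 30649 named rows, 10021 had a symbol found in a separate reference of gene names. Tumours carry the replicate numbers of their labels, R157 to R161 and R162 to R165, and no number occurs in both groups.

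Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3) and low genes removed with filterByExpr (minimum count 10, minimum total 15). The groups were compared with edgeR's quasi-likelihood test with robust dispersion, group as the only term and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.523, so that single genes varied widely between tumours of a group. TMM factors ran from 0.650 in EGFP R162 to 1.25 in EGFP R164, and the median log2 fold change of all genes was -0.03. Normalised CPM are counts per 1000000 of TMM-scaled library size, and log2 CPM used a prior count of 2. A count of 0 allows up to 3 counts, which is 0.164 CPM in the deepest tumour and 0.734 CPM in EGFP R162. Reads had no molecular identifiers, so such floors cover counting error only.

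Before the data were examined, 28 gene lists were written: the CDK12/CDK13 and cyclin K complex, the nuclear RNA exosome and its adaptors, nonsense-mediated decay, cleavage and polyadenylation, DNA damage repair, melanocyte differentiation, neural crest, MAPK feedback, cell cycle, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, interferon and RNA sensing, unfolded protein response, heat shock, immediate early genes, hypoxia and glycolysis, and markers of skeletal muscle, keratinocytes, erythrocytes, macrophages, neutrophils, T and NK lymphocytes, B lymphocytes, fibroblasts, endothelium, nerve and glia, and iridophores and xanthophores. Lists with at least 3 measured genes, 27 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry. A list's score in a tumour is the mean over its genes of log2 CPM minus the gene's mean over the 9 tumours. Scores were compared by exact two-sided permutation over all 126 ways to choose 5 of 9 tumours, where the smallest p is 0.00794. Some genes are in more than a single list, among them csf1ra (macrophage and xanthophore), atf3 (immediate early and unfolded protein) and egr1 (immediate early and MAPK).

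The rule for named genes was also set before the data were examined. It took cdk13, cdk12 and ccnk, then up to 12 called genes in each direction. As there were none, it took the 8 genes with the smallest p on each side that had a gene name rather than a clone name. In each list it took up to 4 genes that passed adjusted over all genes or over the list alone, or otherwise the 2 with the smallest p, given as values. Alternatives set in advance were DESeq2's size factors and upper-quartile factors in edgeR, no filter and a stricter filter (CPM of 1 in 4 tumours), no robust dispersion, DESeq2 1.42.0, limma voom with sample weights, 1 surrogate variable from sva 3.50.0, and leaving out each tumour in turn. Added after seeing the data were the exact test of list scores, the skeletal muscle score as a covariate, the 5 tumours with a muscle score below 0, removal of small noncoding RNA rows, and the ribosomal list without S6 kinases and rpl7l1. A comparison of gene length and a comparison of reads outside genes had been planned and were not run.

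The tests were checked on simulated counts for the 15169 genes of the CDK13 R860Q against EGFP comparison, with 50 genes changed at each of 4 sizes. With 5 false calls over all genes, edgeR recovered 0% of genes at a log2 of 1, 38% at 2, 84% at 3 and 88% at 4. A list shifted by a log2 of 1 was called by camera (adjusted p = 1.78e-12, or 0.0159 with an estimated correlation), and 0 of 26 unshifted lists were. Simulated genes vary independently, so this does not measure false list calls in real tumours. The changed genes together ease the adjusted threshold, so the recovered shares may be too high for data in which few genes change. Figures were drawn with matplotlib 3.10.9.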

Results

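Gene expression was measured in 9 melanomas dissected from zebrafish that lacked p53 and carried BRAF V600E under the melanocyte promoter mitfa. The embryos had been injected with MiniCoopR, a vector that brings back mitfa together with a gene of interest, so that the pigment cells that return also carry that gene. In 5 tumours the vector carried CDK13 R860Q, a mutant of a cyclin-dependent kinase that acts with cyclin K on RNA polymerase II, and in 4 control tumours it carried EGFP. Each tumour gave 1 library of ribosome-depleted total RNA, and the deposited values were read counts for 30649 gene names. Total counts were between 7252950 and 11150732 in the R860Q tumours and between 5518472 and 15120176 in the EGFP tumours. At least 1 read was counted for 26068 genes, and 15169 genes had enough reads to be tested. The gene coding for 7SL RNA, the RNA of the signal recognition particle, took 22.8% ± 4.24 of the counts in R860Q tumours (SD, n = 5) and 23.6% ± 5.27 in EGFP tumours (SD, n = 4), with an exact two-sided permutation p of 0.841. The labels do not say whether each tumour came from its own fish, so p-values measure the spread between these 9 samples.

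The tumours of a group resembled each other little more than tumours of different groups. Pearson correlations of log2 CPM across genes had a median of 0.863 in the 16 pairs within a group (range 0.754 to 0.902) and of 0.833 in the 20 pairs between groups (0.786 to 0.905). No pair agreed within sampling noise, the lowest chi-square per degree of freedom being 47.0, and all 9 libraries were counted as separate samples. The first principal component held 24.5% of the variance and set EGFP R162 (-102) and EGFP R164 (-57.2) apart from the rest (-7.56 to 48.9).

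The vector's gene was the clearest difference between the groups by DESeq2, while by edgeR 2 clone-named genes had a lower adjusted p (0.174, below). The files count human CDK13 on a row of its own, hCDK13, which reached 66.7, 751, 54.8, 162.1 and 16.2 normalised CPM in R860Q tumours R157 to R161, from 895, 7239, 376, 1115 and 114 reads. In EGFP tumours R162 to R165 the row held 2, 1, 0 and 5 reads, and the 0 in EGFP R164 allows up to 0.437 CPM (3 counts, counting error only). Every R860Q tumour was above every EGFP tumour, with an exact two-sided permutation p of 0.00794 on log2 CPM, the smallest that 5 against 4 tumours can give. The log2 fold change was 10.01 ± 1.54 (SE). The adjusted p was 0.303 by edgeR and 9.01e-17 by DESeq2. Zebrafish cdk13 was at 28.6 ± 6.40 CPM in R860Q tumours (SD, n = 5) and 26.1 ± 10.6 in EGFP tumours (SD, n = 4), a log2 difference of 0.13 ± 0.30 (SE, edgeR adjusted p = 0.984).

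**Figure D1:**
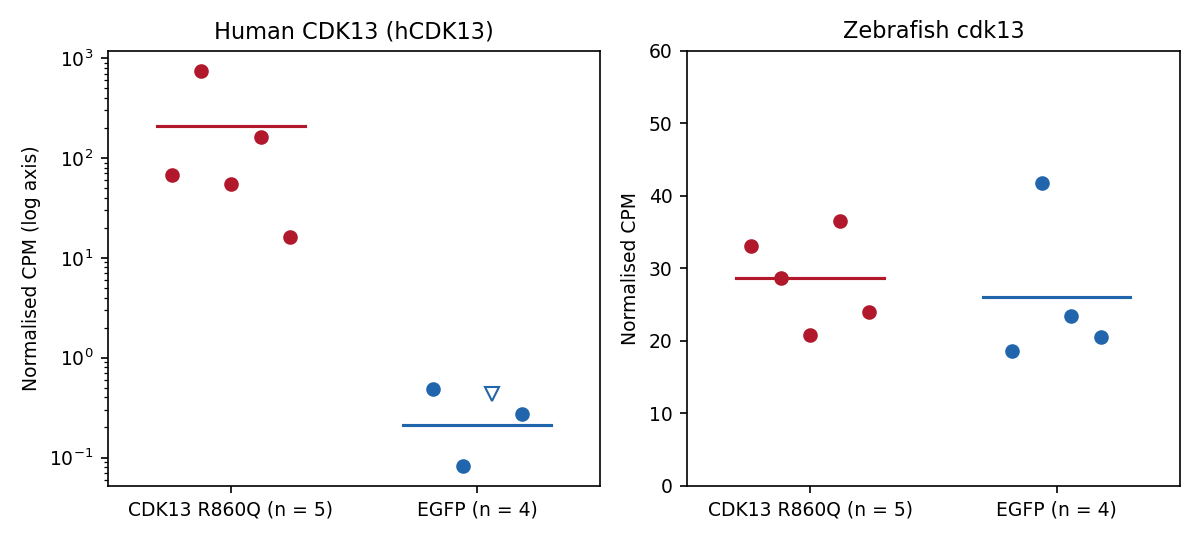
Normalised CPM of human CDK13 (left, log axis) and zebrafish cdk13 (right, linear axis) in 5 CDK13 R860Q and 4 EGFP tumours; each point is a tumour, horizontal lines are group means, and the open triangle marks the 3-count floor of a tumour with 0 reads. Human CDK13 lies between 16.2 and 751 CPM in the R860Q tumours and at or below 0.489 CPM in the EGFP tumours, while the zebrafish gene overlaps between groups.

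The comparison of the groups asks how gene expression differs in melanomas that carry the vector with the mutant kinase. EGFP was the only control. Without tumours given wild-type CDK13, an effect of the mutation cannot be told apart from one of added human CDK13. Among named genes, those with the smallest p-values on the higher side included loxl3b, a lysyl oxidase that crosslinks collagen, at 20.0 ± 4.23 CPM in R860Q and 7.76 ± 1.06 in EGFP tumours (SD, n = 5 and 4), a log2 fold change of 1.36 ± 0.25 (SE). The others were tppp3, a tubulin-binding protein (2.54 ± 0.60), tmx4, a thioredoxin-like membrane protein (1.04 ± 0.25), tagln3b, an actin-binding transgelin (3.17 ± 0.78, or 2.27 without R860Q R159), orai2, a calcium channel subunit (1.25 ± 0.32), cep131, a centrosomal protein (0.97 ± 0.25), and the alpha-globin hbaa2 (3.99 ± 0.96). The named genes on the lower side were mostly secreted immune signals. The chemokine ccl34a.3 was at 0.890 ± 0.590 CPM in R860Q and 6.97 ± 3.15 in EGFP tumours (log2 fold change -2.93 ± 0.53), and its neighbour in name ccl34a.4 at -2.19 ± 0.42. The interleukin 6 family cytokine m17 (-2.32 ± 0.41), interleukin il11b (-2.48 ± 0.46) and the granulocyte colony-stimulating factor csf3a (-2.65 ± 0.51) were on that side as well. So were inpp4b, an inositol phosphatase (-2.15 ± 0.41), st6galnac5b, a sialyltransferase (-2.51 ± 0.50), and chst15, a chondroitin sulfotransferase (-2.21 ± 0.45). These genes did not overlap between the groups, hbaa2 excepted, but genes picked by smallest p tend to be separated, so this adds no support. None passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p between 0.358 and 0.636.

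**Figure D2:**
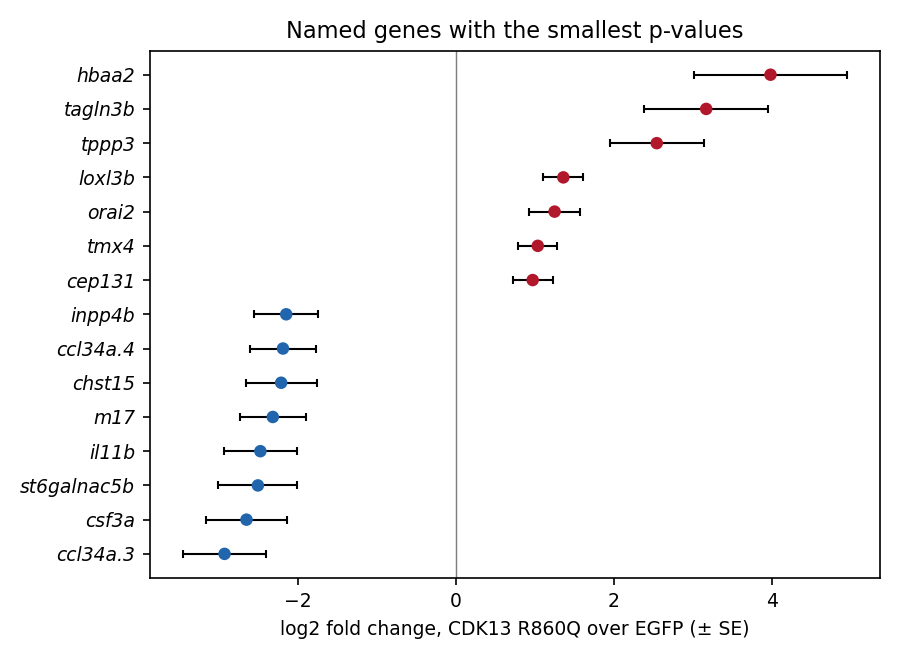
Log2 fold change, CDK13 R860Q over EGFP, of the 15 zebrafish genes named by the rule set before the data were examined (points; bars are ± SE; 5 against 4 tumours; red above and blue below 0). The values run from -2.93 for ccl34a.3 to 3.99 for hbaa2, and none passed edgeR's adjusted threshold, while DESeq2 called all but orai2 and cep131.

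Over all 15169 genes, edgeR called 0 genes higher and 0 lower at an adjusted p under 0.05. The smallest adjusted p, 0.174, was shared by 2 low-expressed clone-named loci singled out after their values were seen: BX548173.1, at 3.12 ± 1.84 CPM in R860Q and 0.0343 ± 0.0412 in EGFP tumours, and BX511078.2, at 1.87 ± 0.701 and 0.0206 ± 0.0412 (SD, n = 5 and 4). At an unadjusted p under 0.05 there were 931 genes, 302 higher and 629 lower, where 758 would come from chance alone. All R860Q tumours were above all EGFP tumours in 95 genes and below in 122, together 1.43% of the genes against 1.59% by chance. DESeq2 called 20 genes higher and 48 lower, and limma voom with sample weights called 0. Simulated tumours of the same number and spread held 50 changed genes at each of 4 sizes. There edgeR recovered 0% of genes changed by a log2 of 1, 38% at 2, 84% at 3 and 88% at 4. Changes of a log2 of 1 were thus below what this comparison could detect. So many changed genes ease the adjusted threshold, and the shares at 2 to 4 may be too high for the real tumours. In these hCDK13, at a log2 of 10.01, did not pass (edgeR adjusted p = 0.303).

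The series title names nuclear RNA surveillance, and the genes of that machinery did not differ detectably. Of 25 measured genes of the nuclear RNA exosome and its adaptors, 12 were on the higher and 13 on the lower side (median log2 fold change -0.01, camera adjusted p = 0.870). Its lowest p-values belonged to skiv2l2, the helicase that feeds the exosome (0.36 ± 0.24 SE), and exosc9, a subunit of its core (-0.66 ± 0.43, between -0.94 without EGFP R163 and -0.39 without EGFP R162). The 14 nonsense-mediated decay factors had a median of 0.06 (10 on the higher side, camera adjusted p = 0.372), with the helicase upf1 at 0.25 ± 0.20. The 22 genes listed as cleavage and polyadenylation factors had a median of 0.09 (14 on the higher side, camera adjusted p = 0.231). Among the genes so listed, scaf11 stood at 0.56 ± 0.33 and the poly(A)-binding protein pabpc1b at 0.75 ± 0.44. The 3 genes of the kinase complex were cdk13 (above), its close relative cdk12 at 0.33 ± 0.26, and cyclin K, ccnk, at 0.21 ± 0.30 (camera adjusted p = 0.309). No member of these 4 lists passed, adjusted over the list alone or over all genes. The transcripts that the exosome degrades, such as prematurely ended ones, are not separate rows of the files and were not measured here.

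Of the immune lists, those of T and NK lymphocytes, B lymphocytes, macrophages and interferon response fell by camera with a preset correlation alone, and that of neutrophils did not. The groups overlapped in these lists: EGFP R163 scored -0.52 for T and NK lymphocytes, -0.59 for B lymphocytes and -0.63 for macrophages, all within the R860Q range, and R860Q R161 scored 0.54 for macrophages, above EGFP R162 (0.35). Of 14 measured T and NK lymphocyte genes, 12 were on the lower side, with a median log2 fold change of -1.49, and the list fell by camera with a preset correlation (adjusted p = 8.42e-10) but not with an estimated correlation (adjusted p = 0.217). By edgeR 9 of these genes passed adjusted over the list alone and 0 over all genes, while DESeq2 called nkl.2 (adjusted p = 2.01e-04). The NK-lysin nkl.2, a pore-forming peptide of cytotoxic cells, was at 13.5 ± 8.03 CPM in R860Q and 250 ± 166 in EGFP tumours (SD, n = 5 and 4; -4.20 ± 0.90 SE), with 9.07 CPM in EGFP R163 inside the R860Q range. The others named by the rule were nkl.4 (-3.36 ± 1.01), the T-cell co-receptor cd4-1 (-1.94 ± 0.62) and the transcription factor tox (-1.52 ± 0.55). A member on the other side, cd3eap at 0.05, codes for an RNA polymerase I subunit despite its name. Of 8 B lymphocyte genes 7 were on the lower side (median -1.40). The list fell by camera (adjusted p = 4.61e-05; adjusted p = 0.270 with an estimated correlation), and blnk, the adaptor of the B-cell receptor, was the gene that passed adjusted over the list alone (-1.67 ± 0.47).

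Of 28 macrophage genes 25 were on the lower side (median -0.75), and the list fell by camera (adjusted p = 3.20e-08; adjusted p = 0.410 with an estimated correlation). The galectin-3-binding protein lgals3bpb, at 47.7 ± 21.8 CPM in R860Q and 198 ± 104 in EGFP tumours (SD, n = 5 and 4; -2.05 ± 0.45 SE), was the member that passed adjusted over the list alone. In the 5 tumours with little muscle RNA, an alternative chosen after seeing the data, the macrophage call was lost (camera adjusted p = 0.0613). These were R860Q R157 and R161 against EGFP R163 to R165, so fewer tumours alone could change a call there. The 20 neutrophil and granulocyte genes did not pass (median -0.23, 14 on the lower side, camera adjusted p = 0.253), with the granule proteoglycan srgn at -1.42 ± 0.45 and the protease adam8a at -0.91 ± 0.38. They passed downward without EGFP R163 (camera adjusted p = 0.00842). Of 35 interferon and RNA sensing genes 28 were on the lower side (median -0.45), and the list fell by camera (adjusted p = 1.23e-06; adjusted p = 0.217 with an estimated correlation). The antiviral GTPase mxb (-1.82 ± 0.38) and the interferon-induced ifit10 (-1.13 ± 0.27) passed adjusted over the list alone. Each was lower in all 5 R860Q tumours than in any EGFP tumour, but both were picked by smallest p, so this adds no support. Taking each tumour's mean score over a list, exact two-sided permutation p-values were 0.0476 for T and NK lymphocytes, 0.0794 for B lymphocytes, 0.135 for macrophages and 0.0238 for interferon genes. After adjustment over 27 lists these were 0.375, 0.398, 0.452 and 0.321.

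**Figure D3:**
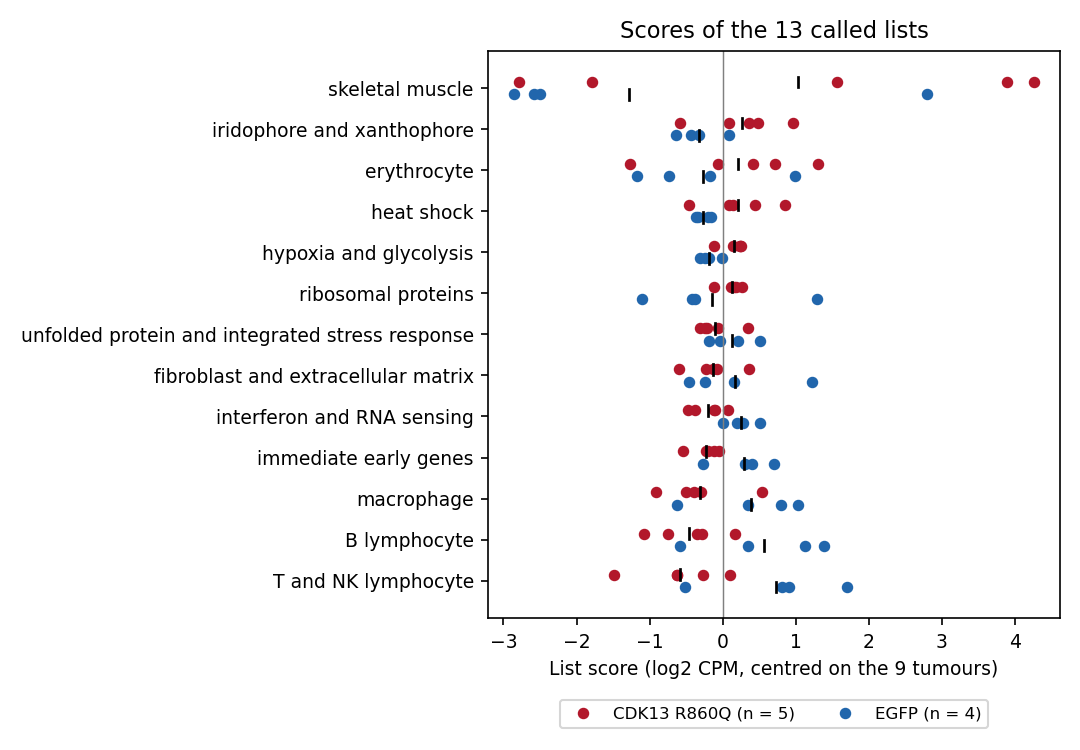
Scores of the 13 gene lists that passed camera with a preset correlation, as mean log2 CPM of the members centred on the 9 tumours; points are tumours (5 CDK13 R860Q in red, 4 EGFP in blue) and black ticks are group means. Skeletal muscle spreads from -2.85 to 4.26.

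Genes of the immediate early response, which cells switch on within minutes of a stimulus, lay mostly on the lower side (25 of 27, median -0.52). The list fell by camera (adjusted p = 4.66e-05, or 0.242 with an estimated correlation). No member passed by edgeR, while DESeq2 called egr3 (adjusted p = 0.0203). The transcription factor egr3 stood at -2.85 ± 0.72 (SE) and the matricellular gene ctgfa at -2.60 ± 0.81, the latter with 334 CPM in EGFP R162 and 12.8 in EGFP R163, and at -1.07 without EGFP R162. The 24 unfolded protein and integrated stress response genes lay close to 0 (median -0.13, 19 on the lower side) and just passed camera (adjusted p = 0.0488; adjusted p = 0.684 with an estimated correlation). The call was lost without R860Q R157, R158, R160 or R161, or EGFP R164 or R165 (adjusted p 0.0763 to 0.527). Its lowest p-values were those of the transcription factors xbp1 (-0.76 ± 0.31) and cebpb (-0.74 ± 0.30). Heat shock genes rose by camera, with 15 of 20 on the higher side and a median of 0.27 (adjusted p = 0.00605; adjusted p = 0.270 with an estimated correlation). The small chaperone hspb1 was at 1.35 ± 0.38, while the co-chaperone dnajb1a stood at -1.02 ± 0.48, but at -0.09 without EGFP R164. The heat shock call was lost with the skeletal muscle score as a covariate (camera adjusted p = 0.0998) and in the muscle-poor tumours (0.395). Hypoxia and glycolysis genes rose by camera as well, with 23 of 35 on the higher side and a median of 0.14 (adjusted p = 0.0192; adjusted p = 0.217 with an estimated correlation). The members with the lowest p-values were glycolytic enzymes rather than oxygen-sensing genes: the enolase eno1a was at 530 ± 93.6 CPM in R860Q and 290 ± 34.7 in EGFP tumours (SD, n = 5 and 4; 0.87 ± 0.27 SE), and the aldolase aldoaa at 1.07 ± 0.35. The hypoxia call was lost without R860Q R157 or R161, or EGFP R163 or R165 (adjusted p 0.0548 to 0.0825).

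Markers of the tumour's own lineage did not pass. The 22 melanocyte differentiation and pigment genes had a median of -0.15 (15 on the lower side, camera adjusted p = 0.202), with the receptor mchr2 at -2.25 ± 0.69 (SE; -1.23 without EGFP R162) and the receptor tyrosine kinase kita at -0.90 ± 0.50 (-0.44 without EGFP R165). In the 21 neural crest and melanoma initiation genes the median was 0.04 and the mean -0.05 (camera adjusted p = 0.835), with erbb3a at -1.29 ± 0.42 and sox9b at -2.19 ± 0.94 (-0.45 without EGFP R164). The 20 MAPK pathway feedback genes had a median of -0.06 (camera adjusted p = 0.983), with mycb at -0.62 ± 0.31 and etv4 at 0.64 ± 0.33. Of 46 cell cycle and DNA replication genes 33 were on the higher side, by little (median 0.09, camera adjusted p = 0.309; e2f7 0.52 ± 0.30, stmn1a 0.57 ± 0.44, but 0.24 without R860Q R160). The 36 DNA damage repair genes had a median of 0.10 (camera adjusted p = 0.218), with the damage-response scaffolds tp53bp1 at 0.98 ± 0.32 and mdc1 at 0.98 ± 0.38, neither of which passed. With a single tumour left out, melanocyte genes passed downward without R860Q R161 (camera adjusted p = 0.00535), and cell cycle (9.83e-05) and repair genes (0.0393) passed upward without R860Q R159. Markers of the other pigment cells, iridophores and xanthophores, rose by camera: 17 of 20 were on the higher side, with a median of 0.81 (adjusted p = 9.40e-05; adjusted p = 0.217 with an estimated correlation). The homeobox gene alx4b stood at 1.86 ± 0.78 and scarb1, needed for carotenoid uptake, at 2.22 ± 0.95 (0.51 without R860Q R161), and no member passed.

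Skeletal muscle RNA differed between tumours of both groups. All 28 measured muscle genes were on the higher side in R860Q tumours (median 2.23) and the list rose by camera (adjusted p = 1.53e-08; adjusted p = 0.655 with an estimated correlation), but no member had an unadjusted p under 0.05. The giant sarcomere protein ttn.2 stood at 2.59 ± 1.47 (SE) and parvalbumin pvalb3 at 3.48 ± 2.0, or at 5.67 and 8.36 without EGFP R162, and ttn.2 at 1.72 without R860Q R159. The muscle score was 1.56, 4.26 and 3.89 in R860Q R158, R159 and R160 and 2.80 in EGFP R162, and between -2.85 and -1.79 in the other tumours (exact two-sided permutation p = 0.310). Muscle genes took at most 0.478% of the counts of a tumour. Of 33 fibroblast and extracellular matrix genes 25 were on the lower side (median -0.56), and the list just passed camera (adjusted p = 0.0488; adjusted p = 0.782 with an estimated correlation). It was lost without R860Q R158 or R160 (0.0963 and 0.0704) and its direction turned without EGFP R165 (0.589), while its 2 genes with the lowest p-values went the other way: the fibronectin fn1b at 1.04 ± 0.32 and the versican vcana at 1.83 ± 0.60. The 16 erythrocyte genes split evenly, 8 and 8, around a median of 0.07 and just passed camera (adjusted p = 0.0488; adjusted p = 0.782 with an estimated correlation). The globins hbaa2 and hbba2 (3.05 ± 0.83) passed adjusted over the list alone, and the list's call was lost without R860Q R157, R158 or R160, or EGFP R163, R164 or R165 (adjusted p 0.0594 to 0.716). Keratinocyte and epidermis genes (30 measured, median -0.29, camera adjusted p = 0.739; krt93 1.77 ± 0.71, tp63 -0.82 ± 0.41), endothelium genes (24, median -0.02, mean 0.18, adjusted p = 0.231; ecscr 2.84 ± 1.15, but 0.53 without R860Q R159, flt4 1.06 ± 0.58, or 1.99 without EGFP R165) and nerve and glia genes (10, median -0.18, adjusted p = 0.739; s100b -7.06 ± 2.29, tubb5 -0.60 ± 0.27) did not pass. The s100b value came from EGFP R162 alone, and its direction turned without that tumour (0.40). Keratinocyte genes passed downward without EGFP R162 (camera adjusted p = 0.00196), and without EGFP R165 they (0.00205) and endothelium genes (0.00145) passed upward.

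The 85 measured ribosomal protein genes passed camera in the upward direction (adjusted p = 0.0488; adjusted p = 0.888 with an estimated correlation) although their median and mean log2 fold changes were both -0.06. That call was lost without R860Q R158, R160 or R161, or EGFP R163 or R164 (adjusted p 0.0594 to 0.482), and turned downward without EGFP R165 (0.218), but was far stronger upward without EGFP R162 (4.92e-31). The members with the lowest p-values were an S6 kinase-like gene, rps6kc1 (-0.37 ± 0.21 SE), and rpl7l1 (-0.67 ± 0.41; -0.12 without EGFP R162), neither a ribosomal protein, which the symbol pattern took in. Without these and the S6 kinases, an alternative chosen after seeing the data, the list passed upward as well (adjusted p = 0.00964). The 94 nuclear-encoded oxidative phosphorylation genes did not pass (median -0.10, camera adjusted p = 0.801; atp5ib -0.74 ± 0.31, ndufb5 -1.24 ± 0.59, but -0.03 without EGFP R163). Without EGFP R162, which had the highest share of ribosomal protein counts (15.2%), that list passed in the upward direction (adjusted p = 5.46e-04), and without EGFP R165 in the downward direction (0.0274). Mitochondrially encoded genes had 0 reads in every tumour and were not tested. Whether reads of the mitochondrial genome were aligned and counted is not given in the sources used here, so this is no measure of their level.

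Of the 27 lists tested, 13 thus passed camera with a preset correlation, 6 upward and 7 downward. None passed with an estimated correlation, by fry, or by the exact permutation test of the tumours' scores after adjustment. The last had little power, as a single list at the smallest possible p, 0.00794, would be adjusted to 0.214 if no other list were low. With the skeletal muscle score as a covariate, chosen after seeing the data, 7 passed.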

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

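The highest and lowest tumour of each group were examined. A tumour was singled out when its gap to the next, divided by the group's range, exceeded Dixon's critical value at 95%. Of 206 sets of values examined, 14 had such a tumour, where chance alone gives about 5% of the sets.

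EGFP R162 stood apart in 4 of them. Its log2 CPM was 7.94 for rpl7l1 (6.32 to 6.51 in the other EGFP tumours), 6.92 for ttn.2 (1.89 to 2.24) and 4.25 for pvalb3 (-1.64 to -1.41). Its skeletal muscle score was 2.80, with -2.85 to -2.49 in the others. EGFP R165 was far from the other EGFP tumours in ccl34a.4 (log2 CPM 5.65, others 4.49 to 4.61) and in the score of the cleavage and polyadenylation factors (-0.39, others 0.01 to 0.06). EGFP R164 had the highest log2 CPM of the co-chaperone dnajb1a (6.71, others 4.39 to 4.62). EGFP R163 had the lowest log2 CPM of the NK-lysin nkl.2 (3.21, others 8.08 to 8.53).

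Among R860Q tumours, R860Q R158 was lowest in the respiratory complex I gene ndufb5 (log2 CPM 4.14, others 4.94 to 5.17) and in xbp1 (6.52, others 7.38 to 7.59). R860Q R157 was lowest in flt4 (-0.064, others 0.83 to 1.07) and highest in s100b (2.27, others -1.67 to -0.99). The score of the cleavage and polyadenylation factors was -0.25 in R860Q R161 and 0.09 to 0.21 in the others. Ribosomal protein genes took 7.85% of the counts in R860Q R159 and 9.42% to 9.87% in the others.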

How the results depend on the processing

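The exact test of scores, the muscle covariate, the muscle-poor tumours, the removal of noncoding RNA rows and the trimmed ribosomal list were chosen after seeing the data. By edgeR the count of genes past the threshold stayed at 0 on both sides under the other scalings and filters, with a surrogate variable, with the muscle covariate and without noncoding RNA rows, as it did by voom. DESeq2 gave 20 higher and 48 lower. Leaving out single tumours gave 0 higher genes and 0 to 1 lower genes, the gene being grn1 without EGFP R165 (adjusted p = 0.00386). The muscle-poor tumours, R860Q R157 and R161 against EGFP R163 to R165, gave 1 higher gene, sc:d217 (adjusted p = 0.0325). Changes in that setting, here and in the lists below, may come from the fewer tumours rather than from muscle. The count at an unadjusted p under 0.05 ran from 621 to 1521 with single tumours left out, the latter without EGFP R163, and was 1825 of 26068 genes with no filter. The hCDK13 log2 fold change was 8.03 to 10.41 over the alternatives (edgeR and voom adjusted p 0.0614 to 0.710) and 10.07 by DESeq2, which also called 14 of the 16 genes taken by smallest p. The cdk13 log2 fold change was 0.0026 to 0.46. The comparisons of gene length and of reads outside genes were not run, since lengths for the build used and such rows were not among the data used here. No paired analysis was possible because the groups share no replicate numbers. Depth limits the lowest genes, as 3 counts are 0.164 to 0.734 CPM.

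Past camera were 9 to 15 lists with single tumours left out, but 0 with an estimated correlation, 0 by fry, 0 by the exact test and 7 with the muscle covariate. With upper-quartile factors the ribosomal (adjusted p = 0.0596), erythrocyte, fibroblast and unfolded protein lists (each 0.0558) were lost. The unfolded protein list was lost with no filter (0.0757) and the stricter filter (0.0526), and the fibroblast list by voom (0.175). Keratinocyte genes passed downward with the surrogate variable (4.71e-04) and in muscle-poor tumours (4.43e-04), cell cycle genes upward in muscle-poor tumours (0.0266) and neutrophil genes downward by voom (0.0485). Adjusted p-values where a list turned its direction follow, and the cause was not tested. Ranges with tumours left out span all 9 such fits, also those in which the list kept its direction. MAPK feedback turned with upper-quartile factors (0.992), no filter (0.576), voom (0.891) and some single tumours left out (0.368 to 0.988 over all 9). Oxidative phosphorylation turned upward with no filter (0.948), voom (0.696), the surrogate variable (0.00319) and in muscle-poor tumours (6.31e-08), and ranged from 5.46e-04 without EGFP R162 to 0.887 with single tumours left out. Neural crest turned with the surrogate variable (0.985), fry (0.980), the muscle covariate (0.776), muscle-poor tumours (0.293) and tumours left out (0.579 to 0.988). The exosome list turned with the stricter filter (0.994), the exact test (0.968), the muscle covariate (0.593) and tumours left out (0.440 to 0.993). Keratinocyte genes turned with the exact test (0.968), the muscle covariate (0.548) and tumours left out (0.00196 to 0.923, upward at 0.00205 without EGFP R165). The ribosomal list turned with the muscle covariate (0.669) and without EGFP R165 (4.92e-31 upward without EGFP R162 to 0.482 with tumours left out). Melanocyte (0.682) and neutrophil genes (0.843) turned in muscle-poor tumours. With tumours left out, cell cycle (9.83e-05 to 0.923), nerve and glia (0.451 to 0.966) and fibroblast genes (7.05e-04 to 0.589) turned at least once. The fits that turned had 0.755 to 0.923 for cell cycle, 0.755 to 0.966 for nerve and glia and 0.589 for fibroblast genes. Of single genes, s100b was at 1.49 in muscle-poor tumours and ranged from -7.48 to 0.40 with tumours left out.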

Other observations

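The gene families, the core MHC and Hox tests, the genes seen in 1 group only, the immune test and the counts over other splits of the tumours were all chosen or set up after the results were seen. Families of immune signals defined by gene symbol lay mostly on the lower side, but none passed after adjustment over the families. There a single family at the smallest possible exact permutation p would be adjusted to 0.127 if no other were low. Of 20 measured chemokine ligands 19 were on the lower side, with a median log2 fold change of -1.47 (exact permutation p of the score 0.0238, adjusted over 16 families 0.127). The interleukin 8 relative cxcl8b.1 stood at -2.93 ± 0.81 (SE) and ccl34b.8 at -2.47 ± 0.54. Of 14 chemokine receptors 12 were on the lower side (median -0.68, exact permutation p = 0.0159, adjusted 0.127), led by ccr12b.1 at -2.94. Of 13 genes named as interleukins or colony-stimulating factors, a symbol pattern that also took in the receptors il6r and il7r, 9 were on the lower side (median -1.02, exact permutation p = 0.0159, adjusted 0.127). All 6 NK-lysin and perforin genes were on the lower side (median -3.29, exact permutation p = 0.0873, adjusted 0.200). MHC class I genes (8 measured, median -0.16), proteasome subunits other than psmb8a and psmb9a (40, -0.22, a symbol pattern that took in the core MHC genes psmb12 and psmb13a), keratins (11, -0.09), collagens (32, -0.50), tubulins (18, -0.18), heat shock 70 and 90 genes (12, 0.15), claudins (16, -0.36), solute carriers (230, -0.12) and znf genes (182, 0.04) had adjusted exact permutation p-values between 0.381 and 0.984. The 5.8S ribosomal RNA row was at 32.5, 38.1, 60.8, 83.5 and 65.4 CPM in R860Q R157 to R161 and at 75.6, 0, 6.11 and 0 CPM in EGFP R162 to R165 (exact permutation p = 0.119).

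A comparison with other ways to split the 9 tumours into 5 and 4 set the scale for the calls. The real split has 0 genes higher and 0 lower by edgeR (highest others 5 and 72), which all 100 splits drawn, the real one included, must reach, so that nothing follows from it about chance. As many genes at an unadjusted p under 0.05 as the real 931 came from 42 of the splits (highest other 1951), and as many DESeq2 calls as the real 68 from 29 (highest other 553). As many camera lists as the real 13 came from 16 (highest other 18), and each of the 100 splits gave at least 3. Chance cannot be excluded for the last 3 counts. Some splits called several times as many genes as the real one. The highest of many splits lies above most others in any case, so whether a structure other than the group divides the tumours was not tested. The split with 72 lower genes set the 4 tumours rich in muscle RNA against the other 5. The splits with 1951 and 553 genes were the same and exchanged R860Q R161 with EGFP R163, whose hCDK13 reads, 114 and 1, went with their labels. Genes above 1 CPM in every tumour of a group and below 0.5 CPM in every tumour of the other numbered 6, all in R860Q tumours, among them hCDK13, BX511078.2, BX548173.1, CR812923.2 and si:dkey-84h14.1. Of all possible splits 5 gave at least as many (highest other 47), and 6 did when the vector's own gene was left out of the real count. Since this count was set up after such genes were seen and was 1 of 6 tried, chance is not excluded for it either. A true level below 0.5 CPM cannot be shown in EGFP R162, where a count of 0 allows up to 0.734 CPM.

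The lower immune lists could come from muscle or another tissue in the R860Q samples, which would thin out every other cell type alike. Muscle as the diluting tissue would have to make up a large part of the RNA to lower the immune score by 0.80. The genes of the muscle list took at most 0.478% of the counts of a tumour. Their share in pure muscle was not measured, so this does not settle how much RNA came from muscle. Muscle and immune scores may also vary together. The difference in immune score went from -0.80 ± 0.40 to -0.63 ± 0.43 (SE) with the muscle score as a covariate. Dilution by another tissue cannot be told apart from an immune difference: the score of all 4 immune cell lists minus that of the keratinocyte, fibroblast and endothelium lists differed by -0.78 (-0.35 ± 0.38 against 0.44 ± 0.68, SD; exact permutation p = 0.0794). With the neutrophil list left out it differed by -0.99 (exact permutation p = 0.0317). That list was dropped because it did not fall in these same tumours, so the second p decides nothing. A true difference in immune infiltration between the groups, differences between fish unrelated to the vector, and chance stay open.

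The core MHC genes psmb8a, psmb9a, psmb12, psmb13a and tap2a, which cut and carry peptides for antigen presentation, had 0 reads in R860Q R157 to R160 and EGFP R165 and 26 to 226 reads each in R860Q R161 and EGFP R162 to R164. Too few reads would not give this, since at least 25.4 reads would have come from the lowest level seen elsewhere. A weaker interferon response is not excluded by 0 of 35 interferon genes sharing the pattern. Genes read in every tumour, such as ifit10 at 34.4 to 123 CPM, could not share it. Interferon list scores overlapped, at -0.48 to 0.28 in the tumours with 0 reads and -0.38 to 0.52 in the others. Inherited MHC haplotypes too unlike the reference for their reads to be counted stay open, untested on sequence: the only other gene of the files with the pattern, si:dkey-211g8.8, lies on chromosome 19 of GRCz12tu as they do but not next to them, prrt2 on chromosome 12 had the reverse pattern, and a class I gene, mhc1uba, was at 0.489 CPM in EGFP R162 and at 60.8 to 481 in the others. So does a tie to the group: 4 of 5 R860Q and 1 of 4 EGFP tumours were at 0 (Fisher's exact p = 0.206), and the score of the 7 core MHC genes measured differed by -2.55 (exact permutation p = 0.0556, adjusted over the families 0.178).

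Posterior Hox genes differed widely between tumours: the 7 measured genes from hoxc10a to hoxc13b were at 1.66 to 99.9 CPM in R860Q R157, R158, R160 and R161 and at 15.0 to 89.0 in EGFP R163, but at or below 1.89 in R860Q R159, EGFP R162 and EGFP R164, with some of them up to 34.7 in EGFP R165. Tumours from different positions along the body could give this, and cannot be told apart from other causes here: the score of the 2 measured hoxa genes was on the same side of its mean as that of the hoxc genes in 9 of 9 tumours, but that of the 4 hoxd genes in 7. R860Q R159 had a hoxc score of -3.25 and the highest hoxd score, 1.98, EGFP R163 had 3.23 and -0.10, and the labels used here do not give positions. An effect of the vector on the hoxc genes cannot be told apart from chance in these few tumours (exact permutation p = 0.230), and all 18 Hox genes together had an exact permutation p of 0.0794 (adjusted over the families 0.200). The hoxd score differed by 2.67 (exact permutation p = 0.00794), but that cluster was picked for its difference and its p decides nothing.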
